A study of Homo sapiens with 8 samples.

How the data were processed

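Total RNA of HaCaT keratinocytes was measured on 8 one-colour arrays with 60-mer probes, 2 from untreated cells, 3 from cells given 5 cytokines and 3 from cells given the cytokines with Ino-C2-PAF. Per the labels, cells were kept in serum-free medium, RNA was extracted with a column kit after 24 h, and Cy3-labelled cRNA was hybridised. Per the file headers, Agilent Feature Extraction 10.7.3.1 gave each spot a processed signal in units of intensity, with the background subtracted, spatial and multiplicative trends within the array removed and low values replaced by surrogates. The authors did not normalize these values between arrays. The deposited series values are the same intensity values: all 62976 values of each of the 8 arrays were equal to the processed signal. Mean spot and local background signals in the deposited files are intensity as scanned, and were used only for a separate background correction. All arrays share 1 slide and 1 scan. The number of arrays, 2 or 3 per group, limits the precision.

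Values were taken to log2 and the 75th percentile of the non-control spots of each array was subtracted. Of 62976 spots, 58717 were not controls. Spots that the software marked as non-uniform or as population outliers (215 to 312 per array) were left out, and 0 spots were saturated. Spots of 1 probe were averaged, which gave 42405 probes. A probe was used when it was well above background on every array of at least 1 group and had an unmarked spot on every array. This left 23687 probes, and the brightest probe stood for each gene, which left 19287 genes. Symbols came from the RefSeq accession for 24826 probes, from the current symbol for 1188 and from an older symbol for 472, while 15919 probes kept the name in the file. Probe positions are on hg19 per the file headers and are given only where the chromosome matched the reference gene table. Exon and UTR annotation was not used here.

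R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8) fitted the 3 groups in 1 model, with eBayes (5 residual and 1.93 prior degrees of freedom) and the Benjamini-Hochberg correction at 0.05 over all genes, two-sided. A gene that was not well above background on any array of a group is given as a nominal lower bound. Its level there was its own value or, if higher, a floor. The floor was the lowest value of any probe well above background on that array, between -6.89 and -6.27 on the log2 scale. The true level can lie above the level used, so the true fold can be smaller than the bound. The comparisons were cytokines against untreated, cytokines with Ino-C2-PAF against cytokines, and cytokines with Ino-C2-PAF against untreated. The 30 gene lists, with 812 distinct genes measured of which 16 stand in several lists, were tested with camera at a correlation of 0.01, and with the correlation estimated per list beside it. The lists were antimicrobial and S100 genes, chemokines, cytokines and receptors, acute phase and complement, NF-κB targets, STAT3 and oncostatin M targets, interferon-induced genes, antigen presentation, Toll-like receptors, epidermal differentiation, cornified envelope, basal keratinocyte genes, cell cycle, DNA replication, extracellular matrix, cholesterol synthesis, fatty acid and phospholipid metabolism, platelet-activating factor and eicosanoid genes, unfolded protein response, p53, oxidative stress, hypoxia, EGF receptor ligands, lysosome, ribosomal proteins, housekeeping genes, and markers of fibroblasts, melanocytes, immune cells and endothelium. The fit was tested on simulated data in 5 draws with 200 changed genes each. For cytokines against untreated it recovered 64.8% of 1.5-fold and 89.0% of 2-fold changes with 6.25% false calls, and for the Ino-C2-PAF comparison 75.2% and 90.1% with 5.60% false calls. The correlations across genes of the first comparison with the second and the third were set beside 100 draws of simulated unchanged groups, because these comparisons share arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

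Named genes followed a rule fixed in advance. It took, for the first and the second comparison, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, without accessions, LOC and open reading frame names. It added up to 2 genes that rose and 2 that fell with the lowest adjusted p in each list, and CXCL8, CCL20, S100A7, S100A8, S100A9, DEFB4A, IL36G, TLR2, PTAFR, KRT10 and MKI67 whatever their values. Some genes that the rule takes are not reported here. Genes named beyond the rule are marked in the text as chosen after their values were seen.

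Alternatives were normexp background correction with an offset of 50, quantile normalization, a median shift, no filter on dim probes, probes well above background on all arrays, the mean of all passing probes, the deposited table, only the groups compared, eBayes with trend and robust options, array weights, the replicate number or the slide row as a block, only the slide row that holds both groups, a fold of at least 2, and leaving out each array. Where this left 1 array in a group, its spread was assumed to be that of the other groups. For the lists, an estimated correlation was planned and fry was added later. Replicate numbers were not taken as pairs. A scan of 337 gene families by symbol, with camera, was also added later. Accession, LOC and open reading frame names were kept in the tests but are not named, because the rule leaves them out.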

Results

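RNA of HaCaT cells, an immortalised human keratinocyte line, was measured on 8 one-colour oligonucleotide arrays that shared 1 slide. Untreated cells gave 2 arrays. Cells given a mixture of oncostatin M, TNF-α, IL-22, IL-17 and IL-1α, each at 2 ng/ml, gave 3 arrays. Cells given the same mixture with 5 µM Ino-C2-PAF, a synthetic inositol-bearing phospholipid related to platelet-activating factor, gave 3 arrays, and all cells were harvested after 24 h. The arrays come from independent experiments per the labels. The 75th percentile of the signal lay between 1071 and 1300 intensity units per array, and 54.0% to 58.0% of the probes were well above background. The number of arrays limits the precision. Across genes, arrays of 1 group correlated at r between 0.9954 and 0.9970, untreated and cytokine arrays between 0.9925 and 0.9939, and cytokine arrays with and without Ino-C2-PAF between 0.9831 and 0.9858. The first principal component held 64.2% of the variance and set the Ino-C2-PAF arrays apart from the other two groups. Of 34809 gene names on the array, 19287 were tested. Changes are given on the log2 scale with their standard error (±, SE), and adjusted p values are from limma with the Benjamini-Hochberg correction. A change from or to a level not well above background on any array of a group is given as a nominal lower bound, "at least". The true fold can be smaller, because the undetected level is uncertain. The arrays of the compared groups did not overlap for any of the 106 named genes called with cytokines, which in large part follows from how they were chosen. The same held for 158 of the 159 named genes called when Ino-C2-PAF was added, with TLR1 as the exception. It also held for the 168 called between Ino-C2-PAF arrays and untreated cells.

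The first comparison asked what the cytokine mixture did to the keratinocytes. Complement and acute-phase genes rose: C1S and C1R, proteases that start the classical complement pathway, rose by 2.15 ± 0.05 (adjusted p = 1.3e-05) and 1.96 ± 0.05 (adjusted p = 1.4e-05) in 3 stimulated against 2 untreated arrays. Haptoglobin (HP), a haemoglobin-binding plasma protein, rose by 2.72 ± 0.23 (adjusted p = 0.0016). The mitochondrial superoxide dismutase SOD2, an NF-κB target, rose by 2.01 ± 0.05 (adjusted p = 1.4e-05), and SOCS3, a feedback inhibitor of cytokine receptors that use STAT3, by 1.70 ± 0.11 (adjusted p = 5.7e-04). The serine protease inhibitors SERPINB3 and SERPINB4, which are high in inflamed squamous epithelium, rose by 3.38 ± 0.14 and 3.30 ± 0.13. The calcium-binding alarmins S100A8 and S100A9 rose by 2.09 ± 0.16 and 2.62 ± 0.22. Involucrin (IVL), a precursor of the cornified envelope, fell by 2.44 ± 0.26 on the log2 scale (adjusted p = 0.0033).

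Other large rises were those of SCN2B, a sodium channel subunit, which was at least 45.7-fold higher (adjusted p = 1.4e-05), and of CHI3L2, a chitinase-like protein, at least 6.53-fold higher. The haptoglobin-related gene HPR was at least 6.23-fold higher and the lipid droplet protein gene PLIN5 at least 3.75-fold. Probes were not realigned, so signal shared between HP and HPR, or between SERPINB3 and SERPINB4, was not excluded. The magnesium channel gene TRPM6 was at least 2.49-fold higher. NNMT, which methylates nicotinamide, rose by 2.90 ± 0.13, and EBI3, a subunit of IL-27, by 2.19 ± 0.08. Large falls were those of DOCK8, a guanine nucleotide exchange factor, at least 7.11-fold lower, and of the epithelial protease TMPRSS11E, at least 3.75-fold. The matrix protease MMP10 was at least 3.40-fold lower, the tachykinin gene TAC4 at least 2.88-fold and the phosphodiesterase PDE6A at least 2.72-fold. PDZK1, a scaffold protein, fell by 1.97 ± 0.31, and ALOX5AP, which leukotriene synthesis needs, fell by 1.79 ± 0.36 on the log2 scale. The transcription factor BATF fell by 1.79 ± 0.26, PHGR1 by 1.75 ± 0.30 and the keratin KRT4 by 1.61 ± 0.26 on the log2 scale. On hg19, the probe of SCN2B lay on chromosome 11 from 118033571 to 118033630 and that of C1S on chromosome 12 from 7178093 to 7178152. The probe of IVL lay on chromosome 1 from 152883972 to 152884031 and that of DOCK8 on chromosome 9 from 465051 to 465110. Exon annotation was not used here.

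By list, 12 of 22 acute-phase and complement genes rose (16 rose and 1 fell when adjusted over the list alone), with a median of 0.63, or 0.37 at the lowest of 4 scalings (camera adjusted p = 3.1e-15, and adjusted p = 0.109 with an estimated correlation). Of 44 interferon-induced genes, 27 rose (35 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 7.2e-25, and adjusted p = 0.226 with an estimated correlation). Among them, the oligoadenylate synthetase-like gene OASL rose by 1.14 ± 0.06 and the membrane protein gene IFITM3, which hinders virus entry, by 0.80 ± 0.06. Of 28 STAT3 and oncostatin M targets, 15 rose and PIM1 fell (18 and 2 adjusted over the list alone), with a median of 0.35. That list (camera adjusted p = 2.9e-13) was the 1 list of the comparison still called with an estimated correlation (adjusted p = 0.0395). Of 28 antigen presentation genes, 12 rose (13 adjusted over the list alone; camera adjusted p = 1.5e-12, and adjusted p = 0.226 with an estimated correlation). HLA-DMB and HLA-DMA, which load peptides onto class II molecules, rose by 1.33 ± 0.11 and 0.97 ± 0.07, and their transactivator CIITA by 0.95 ± 0.11.

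Among 17 chemokines, 4 rose, CCL2, CCL7, CCL5 and CXCL1 (6 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0060, and adjusted p = 0.295 with an estimated correlation). CCL2 and CCL7, which attract monocytes, rose by 1.55 ± 0.09 and 1.93 ± 0.16. Among 43 cytokines and receptors, 10 rose and TGFB2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 2.0e-04, and adjusted p = 0.226 with an estimated correlation). IL6, a driver of the acute-phase response, rose by 1.38 ± 0.12. Of 18 antimicrobial and S100 genes, 7 rose (9 rose and 1 fell adjusted over the list alone), with a median of 0.44 (camera adjusted p = 6.6e-05, and adjusted p = 0.323 with an estimated correlation). Of 30 NF-κB targets, 4 rose, SOD2, ZC3H12A, ICAM1 and RELB (8 adjusted over the list alone; camera adjusted p = 2.7e-04, and adjusted p = 0.226 with an estimated correlation). Of 36 epidermal differentiation genes, 6 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -0.20, or -0.13 at the scaling nearest to 0 (camera adjusted p = 0.0026, and adjusted p = 0.323 with an estimated correlation). The proteases KLK7 and KLK6, which act in skin shedding, fell by 1.36 ± 0.08 and 1.06 ± 0.07. By contrast, ALOX12B, a barrier lipoxygenase, and TGM1, the transglutaminase that cross-links the cornified envelope, rose by 1.29 ± 0.08 and 1.05 ± 0.07. Of 32 basal and hyperproliferation keratinocyte genes, 8 rose, and the keratins KRT4, KRT7, KRT13 and KRT15 fell (15 and 7 adjusted over the list alone; camera adjusted p = 0.0016, and adjusted p = 0.226 with an estimated correlation). Of 28 cholesterol synthesis genes, 5 rose, ACAT2, FDPS, HMGCS1, MSMO1 and SQLE (12 adjusted over the list alone; camera adjusted p = 8.9e-07, and adjusted p = 0.226 with an estimated correlation). CCL5, CXCL1, ICAM1, RELB, KRT7, KRT13, FDPS, MSMO1 and SQLE were singled out after their values were seen.

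Further lists also passed camera. Of 19 Toll-like receptor and pattern recognition genes, LY96, CD14 and MYD88 rose and TLR1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.033, and adjusted p = 0.323 with an estimated correlation). Of 37 unfolded protein and stress response genes, VLDLR, HYOU1 and CRELD2 rose (7 adjusted over the list alone; camera adjusted p = 1.4e-05, and adjusted p = 0.388 with an estimated correlation). Of 29 oxidative stress and NRF2 genes, 5 rose, AKR1C1, AKR1C3, AKR1B10, ABCC3 and DUOXA2, and TKT fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.0060, and adjusted p = 0.294 with an estimated correlation). Of 31 hypoxia and glycolysis genes, 5 rose, among them the glucose transporter SLC2A3 and hexokinase HK2, and P4HA1 and BNIP3L fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.021, and adjusted p = 0.272 with an estimated correlation). Of 9 immune cell markers, CD68 rose (1 adjusted over the list alone; camera adjusted p = 0.044, and adjusted p = 0.326 with an estimated correlation). Neither of the proliferation lists had a member past the limma threshold, with 0 of 40 in each. The DNA replication list leaned up, with 11 genes higher at unadjusted p under 0.05, a median of 0.11 and camera adjusted p = 1.2e-05 (adjusted p = 0.396 with an estimated correlation). The cell cycle and mitosis list leaned down, with 7 genes lower and 1 higher at unadjusted p under 0.05, a median of -0.07 and camera adjusted p = 0.015 (adjusted p = 0.454 with an estimated correlation). CD14, MYD88, HYOU1, CRELD2, P4HA1, BNIP3L and the oxidative stress genes were singled out after their values were seen.

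The remaining 12 lists did not pass camera with cytokines. Among 41 extracellular matrix genes, 9 rose and 5 fell (10 and 9 adjusted over the list alone; camera adjusted p = 0.514). Among 36 platelet-activating factor and eicosanoid genes, 5 rose and 2 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.671). The median of -0.03 and mean of -0.02 lay below 0 while the test leaned up. The leukotriene B4 receptor LTB4R rose by 1.23 ± 0.06 and the lysophospholipid acyltransferase LPCAT1 by 1.03 ± 0.07. Among 44 fatty acid and phospholipid genes, 3 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.514). Among 30 EGF receptor ligand and growth factor genes, 2 rose (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.862). Among 31 p53 and apoptosis genes, 1 rose and 2 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.664). Among 34 lysosome and autophagy genes, 2 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.930). Among 18 housekeeping genes, 1 rose (1 adjusted over the list alone; camera adjusted p = 0.173). None of the 30 ribosomal protein genes was called by limma, 0 had an unadjusted p under 0.05, and the median of -0.01, whose sign changed between scalings, and mean of 0.01 differed in sign (camera adjusted p = 0.862). The late cornified envelope and small proline-rich list had 0 of 17 genes called by limma, with 3 higher and 1 lower at unadjusted p under 0.05 (camera adjusted p = 0.068, and adjusted p = 0.396 with an estimated correlation). At the preset correlation, that list passed camera with the replicate number as a block (adjusted p = 0.023), with the slide row as a block (adjusted p = 0.029), and without control 1 (0.035), cytokines 3 (0.029), Ino-C2-PAF 2 (0.046) or Ino-C2-PAF 3 (0.021). For this comparison, the slide row block and leaving out cytokines 3 are the same fit, because cytokines 3 was the only array of these groups in the second row. Of the markers of other cell types, 1 of 8 fibroblast genes rose and 3 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.375). Likewise 1 of 5 melanocyte genes rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.930). Finally, 1 of 4 endothelial genes rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.530).

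Over all 19287 genes, 571 rose and 549 fell with cytokines, 98 and 78 of them at least 2-fold. Groups did not overlap for 41.0% of all genes, where chance gives 20% for 3 against 2 arrays. Among genes named whatever their values, S100A7 rose by 1.47 ± 0.28 (adjusted p = 0.031), the IL-36 cytokine gene IL36G by 1.12 ± 0.19 (adjusted p = 0.020), and the suprabasal keratin KRT10 fell by 0.28 ± 0.05 on the log2 scale (adjusted p = 0.020). The chemokine CCL20 (-0.12 ± 0.23, adjusted p = 0.84), the defensin DEFB4A (0.43 ± 0.23, adjusted p = 0.34), TLR2 (0.23 ± 0.05, adjusted p = 0.053), the platelet-activating factor receptor PTAFR (0.05 ± 0.11, adjusted p = 0.87) and the proliferation marker MKI67 (-0.10 ± 0.17, adjusted p = 0.81) did not pass the test. CXCL8 had 1 probe, which was not well above background on any of the 8 arrays, and was not tested.

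With only 2 untreated arrays, many of these calls ended when 1 array was left out. Without control 2 BATF stood at -1.79, ALOX5AP at -1.71, PDZK1 at -1.79, IL36G at 1.01 and S100A7 at 1.16. MMP10 stood at -2.01, computed from cytokine arrays on which it was not well above background, so its size is uncertain. Without control 1 the counts were 310 and 203, and without control 2 they were 251 and 186. Without cytokines 1 they were 348 and 328, without cytokines 2 they were 289 and 251, and without cytokines 3 they were 327 and 271. The slide row block is here the same fit as leaving out cytokines 3. Leaving out either control array ended the calls of BATF (highest adjusted p = 0.076), MMP10 (0.066), PDZK1 (0.10), PHGR1 (0.12), IL36G (0.13), S100A7 (0.16), KRT10 (0.11), KRT15 (0.13) and ALOX5AP (0.16). It also ended those of PIM1 (0.18), TGFB2 (0.12), TLR1 (0.17), MYD88 (0.14), AKR1B10 (0.12), TKT (0.079), CRELD2 (0.14), BNIP3L (0.18) and CD68 (0.19). Leaving out cytokines 1 or cytokines 2 also ended the calls of S100A7, ALOX5AP or IL36G, among others. PLIN5 lost its call without any cytokine array (highest adjusted p = 0.097, without cytokines 2), control 1 or Ino-C2-PAF 2, KRT4 without control 1 (0.098) or cytokines 2, and LY96 without control 2 (0.077), cytokines 1 or cytokines 2. List calls ended without control 2 for the chemokines (adjusted p = 0.11), DNA replication (0.22), Toll-like receptors (0.095), hypoxia (0.095) and immune cell markers (0.059). The cell cycle list was not called without control 1 (0.57), nor were the immune cell markers (0.16), which also lost their call without cytokines 3 (0.14) and with the slide row as a block (0.14). The Toll-like receptor list was not called without cytokines 1 (0.060) or cytokines 2 (0.074), nor the hypoxia list after quantile normalization (0.060). With the 4 arrays of the first slide row alone, 57 genes rose and 34 fell, and the limma calls of HPR (adjusted p = 0.051), S100A9 (0.056), IL6 (0.061), CIITA (0.098), IVL (0.056), IFITM3 (0.056), ZC3H12A (0.051), TAC4 (0.051) and TMPRSS11E (0.076) ended. After normexp background correction with an offset of 50, the changes of dim genes were smaller, at 1.53 for HP, 1.01 for CCL7, 0.67 for IL36G, -0.50 for ALOX5AP, -0.68 for BATF and -0.96 for PDZK1.

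The second comparison asked what Ino-C2-PAF changed in cells that received the cytokines. The monocyte attractant CCL2 fell by 3.54 ± 0.08 on the log2 scale (adjusted p = 3.3e-06) in 3 arrays with against 3 without Ino-C2-PAF, and IL6 fell by 1.98 ± 0.10 (adjusted p = 3.0e-05). The class II transactivator CIITA fell by 2.39 ± 0.10 (adjusted p = 1.5e-05). The mitotic topoisomerase TOP2A fell by 1.07 ± 0.05 (adjusted p = 1.8e-05). KLF2, a transcription factor that restrains inflammation in several cell types, rose by 4.88 ± 0.08 (adjusted p = 6.7e-07), and the cytokine LIF by 2.43 ± 0.08 (adjusted p = 9.0e-06). SPRR2C and SPRR2D of the small proline-rich family rose by 2.21 ± 0.14 and 2.10 ± 0.13, and DUSP4, a phosphatase induced by MAP kinase signalling, by 2.05 ± 0.07.

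Several genes were well above background with Ino-C2-PAF but on none of the cytokine arrays. The growth factor BMP6 was at least 59.4-fold higher (adjusted p = 3.8e-06), MMP10 at least 36.8-fold and the IL-33 receptor IL1RL1 at least 24.2-fold. The proton pump ATP12A was at least 21.3-fold higher, the cytokine IL24 at least 19.1-fold, the citrate transporter SLC13A5 at least 16.1-fold and the gasdermin GSDMA at least 14.2-fold. B3GAT1, which makes the HNK-1 carbohydrate, rose by 5.35 ± 0.19 and the decoy receptor IL13RA2 by 5.29 ± 0.32. The vasoconstrictor EDN2 was at least 21.9-fold lower (adjusted p = 6.1e-05). HLA-DOA, a class II chaperone, fell by 2.86 ± 0.36, the tetraspanin TSPAN8 by 2.64 ± 0.24, CCN5 (WISP2 in the file) by 2.63 ± 0.10, and PSAPL1 by 2.61 ± 0.11 on the log2 scale. CCL7 fell by 2.55 ± 0.15, the immune checkpoint ligand VTCN1 by 2.44 ± 0.07, the placental alkaline phosphatase ALPP by 2.33 ± 0.09 and HLA-DMB by 2.21 ± 0.10 on the log2 scale. On hg19, the probe of CCL2 lay on chromosome 17 from 32584050 to 32584109 and that of KLF2 on chromosome 19 from 16438246 to 16438305. The probe of BMP6 lay on chromosome 6 from 7881395 to 7881454.

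The interferon, antigen presentation, acute-phase and chemokine lists fell with Ino-C2-PAF. Of 44 interferon-induced genes, 38 fell and ISG20 rose (40 and 1 adjusted over the list alone), with a median of -0.76 (camera adjusted p = 3.3e-15, and adjusted p = 0.269 with an estimated correlation). Among them, the transcription factor IRF1 fell by 1.30 ± 0.08 and IFIT2 by 0.95 ± 0.05. The death ligand TNFSF10, from the cytokine and receptor list, fell by 1.62 ± 0.09. Of 28 antigen presentation genes, 23 fell (24 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 1.4e-12, and adjusted p = 0.251 with an estimated correlation). Of 22 acute-phase and complement genes, 16 fell and CD55 and SERPINA1 rose (16 and 2 adjusted over the list alone), with a median of -0.56 (camera adjusted p = 5.9e-05, and adjusted p = 0.260 with an estimated correlation). C1R fell by 1.05 ± 0.05, C1S by 0.91 ± 0.04 and the complement protease CFD by 1.03 ± 0.04. Of 17 chemokines, 9 fell and CXCL5 rose (9 and 3 adjusted over the list alone), with a median of -0.52, or -0.34 at the scaling nearest to 0 (camera adjusted p = 0.0080, and adjusted p = 0.269 with an estimated correlation).

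Proliferation lists fell as well. All 40 cell cycle and mitosis genes fell (40 adjusted over the list alone), with a median of -0.83 (camera adjusted p = 1.5e-23, and adjusted p = 0.117 with an estimated correlation). The mitotic kinase PLK1 fell by 1.08 ± 0.05 and MKI67 by 0.92 ± 0.15. Of 40 DNA replication genes, 35 fell and CDC6, which loads the replicative helicase, rose (36 and 1 adjusted over the list alone), with a median of -0.50 (camera adjusted p = 9.6e-14, and adjusted p = 0.269 with an estimated correlation). The transcription factor E2F2 fell by 1.74 ± 0.08 and thymidine kinase TK1 by 0.78 ± 0.05.

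Lists of lipid synthesis, growth signalling and the cornified envelope rose. Of 28 cholesterol synthesis genes, 23 rose and PMVK and SCAP fell (24 and 2 adjusted over the list alone), with a median of 0.86 (camera adjusted p = 1.6e-12, and adjusted p = 0.198 with an estimated correlation). ACAT2, which condenses acetyl-CoA, rose by 1.35 ± 0.04. Of 44 fatty acid and phospholipid genes, 22 rose and 5 fell (23 and 6 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.0011, and adjusted p = 0.117 with an estimated correlation). ACLY and ACSS2, which supply cytosolic acetyl-CoA, rose by 1.45 ± 0.05 and 1.44 ± 0.07, and ACSL5, which activates long-chain fatty acids, fell by 1.40. Of 30 EGF receptor ligand and growth factor genes, 21 rose and 5 fell (21 and 5 adjusted over the list alone), with a median of 0.97 (camera adjusted p = 4.4e-06, and adjusted p = 0.198 with an estimated correlation). The EGF receptor ligand AREG rose by 1.80 ± 0.15. FOSL1, an AP-1 subunit that belongs to the STAT3 list and not to this one, rose by 2.59 ± 0.07. Of 17 late cornified envelope and small proline-rich genes, 11 rose and LCE5A fell (11 and 1 adjusted over the list alone), with a median of 1.33, or 0.51 at the lowest of 4 scalings (camera adjusted p = 6.8e-05, and adjusted p = 0.198 with an estimated correlation). Of 29 oxidative stress and NRF2 genes, 15 rose and 4 fell (16 and 4 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.028, and adjusted p = 0.336 with an estimated correlation). SQSTM1, an autophagy adaptor, rose by 0.43 ± 0.04 and the exporter ABCC2 by 1.09 ± 0.10. Of 4 endothelial markers, CLDN5, ROBO4 and VWF rose (3 adjusted over the list alone; camera adjusted p = 0.014, and adjusted p = 0.198 with an estimated correlation). CD55, SERPINA1 and ROBO4 were singled out after their values were seen.

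**Figure D1:**
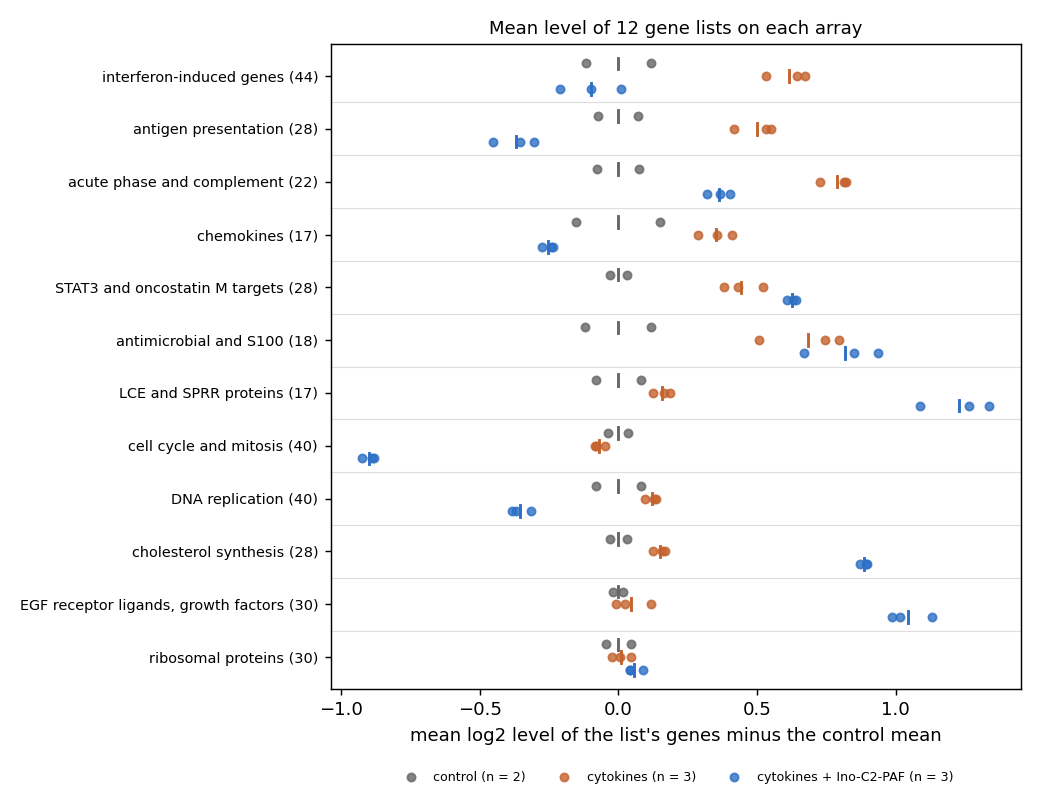
Mean level of 12 gene lists on each of the 8 arrays, on the log2 scale as the difference from the mean of the untreated arrays; each point is 1 array and each vertical bar a group mean. The cell cycle list lay at -0.92, -0.89 and -0.88 on the Ino-C2-PAF arrays, and the cholesterol synthesis list at 0.89, 0.89 and 0.87.

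The other 18 lists did not pass camera when Ino-C2-PAF was added, and many had members on both sides. Of 18 antimicrobial and S100 genes, 6 rose and 6 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.781), with a median of -0.13, a mean of 0.14 and a test that leaned up. RNASE7, an antimicrobial ribonuclease, rose by 1.77 ± 0.07 and DEFB4A by 1.44 ± 0.20, while the constitutive defensin DEFB1 fell by 1.43 ± 0.20. Of 43 cytokines and receptors, 17 rose and 12 fell (17 and 16 adjusted over the list alone; camera adjusted p = 0.50), with a median of -0.02 and a mean of 0.62. IL36G rose by 1.64 ± 0.17. Of 36 epidermal differentiation genes, 9 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.893), with a median of -0.01 and a mean of 0.09. ALOX12B rose by 1.72 ± 0.08. Of 41 matrix genes, 14 rose and 10 fell (16 and 11 adjusted over the list alone; camera adjusted p = 0.699), with a median of -0.03 and a mean of 0.30. Of 36 platelet-activating factor and eicosanoid genes, 9 rose and 12 fell (9 and 12 adjusted over the list alone; camera adjusted p = 0.603). PTGS2, the inducible prostaglandin synthase, rose by 1.09 ± 0.09. Of 28 STAT3 targets, 12 rose and 10 fell (12 and 10 adjusted over the list alone; camera adjusted p = 0.559), and SOCS3 fell by 1.03 ± 0.10. Of 19 Toll-like receptor genes, 7 rose and 8 fell (8 and 9 adjusted over the list alone; camera adjusted p = 0.695). TLR3, a sensor of double-stranded RNA, fell by 1.46 ± 0.08 on the log2 scale. Of 30 NF-κB targets, 8 rose and 7 fell (10 and 8 adjusted over the list alone; camera adjusted p = 0.838). Of 32 basal keratinocyte genes, 12 rose and 10 fell (12 and 11 adjusted over the list alone; camera adjusted p = 0.749), with a median of -0.04 and a mean of 0.11.

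The unfolded protein list had 13 genes that rose and 11 that fell among 37 (14 and 11 adjusted over the list alone; camera adjusted p = 0.781), with a median of -0.002, whose sign changed between scalings, and a mean of 0.10. The p53 list had 11 and 7 among 31 (11 and 7 adjusted over the list alone; camera adjusted p = 0.529), and the death receptor TNFRSF10A rose by 1.33 ± 0.07. The hypoxia list had 14 and 11 among 31 (15 and 13 adjusted over the list alone; camera adjusted p = 0.655). The lysosome list had 13 and 7 among 34 (14 and 7 adjusted over the list alone; camera adjusted p = 0.394). The housekeeping list had 3 and 8 among 18 (4 and 8 adjusted over the list alone; camera adjusted p = 0.50). None of the 30 ribosomal protein genes was called by limma, with 1 higher at unadjusted p under 0.05 (camera adjusted p = 0.390). Fibroblast markers had 2 and 3 among 8 (2 and 3 adjusted over the list alone; camera adjusted p = 0.781). Melanocyte markers had 0 and 3 among 5 (0 and 3 adjusted over the list alone, 0 higher at unadjusted p under 0.05; limma calls, camera adjusted p = 0.094). Immune cell markers had 3 and 0 among 9 (3 and 0 adjusted over the list alone, 0 lower at unadjusted p under 0.05; camera adjusted p = 0.390). The 3 immune cell markers were CD68, ITGAX and LAPTM5, the last singled out after its values were seen.

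Over all genes, 4056 rose and 3644 fell when Ino-C2-PAF was added, 478 and 374 of them at least 2-fold, and the groups did not overlap for 52.2% of genes, where chance gives 10%. CCL20 (0.39 ± 0.20, adjusted p = 0.17), KRT10 (-0.08 ± 0.04, adjusted p = 0.21), S100A7 (-0.35 ± 0.25, adjusted p = 0.33), IVL (0.23 ± 0.23, adjusted p = 0.48), SOD2 (0.14 ± 0.05, adjusted p = 0.052) and SERPINB3 (-0.24 ± 0.13, adjusted p = 0.19) did not pass the test. The brightest probe of PTAFR gave -0.03 ± 0.10 (adjusted p = 0.84), while its other probe gave 0.70 ± 0.09 (adjusted p = 9.0e-04). S100A9 fell by 0.70 ± 0.20 on the log2 scale (adjusted p = 0.028), S100A8 by 0.45 ± 0.14 (0.041) and TLR2 by 0.15 ± 0.05 (0.042). The calls of S100A9 and S100A8 ended without cytokines 1, cytokines 2 or any Ino-C2-PAF array, with highest adjusted p of 0.089 and 0.12 without cytokines 2, and TLR2 lost its call without any cytokine or Ino-C2-PAF array (0.12 without cytokines 2). CXCL5 lost its call without any 1 of the cytokine arrays (0.093 without cytokines 1).

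The slide row was partly shared with treatment, because the first row held both untreated arrays with cytokines 1 and 2, and the second row held cytokines 3 with the Ino-C2-PAF arrays. With the row as a block, 2239 genes rose and 2067 fell, and within the second row alone, which sets 3 arrays against 1, 1255 rose and 1099 fell. The block ended the call of VIM, a mesenchymal filament gene that rose by 2.34 ± 0.47 (adjusted p = 0.10 with the block). The block and the second row alone both ended the calls of CDC6, S100A8, S100A9 and HP, with highest adjusted p of 0.27, 0.45, 0.30 and 0.21. The calls of HLA-DOA (0.079), MKI67 (0.089) and DEFB1 (0.071) ended within the second row alone. After normexp background correction with an offset of 50, the changes of dim genes were smaller, at 3.01 for IL13RA2, 0.78 for VIM, -1.23 for CCL7, -1.13 for CCN5, -1.04 for TSPAN8 and -1.34 for HLA-DOA.

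The third comparison asked what remained of the cytokine state with Ino-C2-PAF, against untreated cells. No group received Ino-C2-PAF without cytokines, so a difference here can hold a remaining cytokine effect, an effect of Ino-C2-PAF itself or both. The untreated arrays all lay in the first slide row and the Ino-C2-PAF arrays all in the second. SOD2 stayed higher by 2.15 ± 0.05 (adjusted p = 2.7e-06), SERPINB3 by 3.14 ± 0.14, S100A9 by 1.92 ± 0.22, S100A8 by 1.64 ± 0.16 and C1S by 1.24 ± 0.05, and IVL stayed lower, at -2.21 ± 0.26 (3 against 2 arrays). CCL2 stood below its untreated level, at -1.99 ± 0.09 (adjusted p = 1.5e-05), as did CIITA (-1.45 ± 0.11), HLA-DMB (-0.88 ± 0.11), IL6 (-0.60 ± 0.12) and CCL7 (-0.62 ± 0.16). On the array scale, log2 signal less the 75th percentile, CCL2 stood at 3.75 ± 0.12 (SD, n = 2) in untreated cells, 5.30 ± 0.03 (SD, n = 3) with cytokines and 1.76 ± 0.13 (SD, n = 3) with Ino-C2-PAF. IL36G (2.76 ± 0.19), DEFB4A (1.87 ± 0.23), MMP10 (3.44 ± 0.28) and KLF2 (4.86 ± 0.08) were higher than in untreated cells, and TOP2A (-1.11 ± 0.05), MKI67 (-1.02 ± 0.17) and KRT10 (-0.36 ± 0.05) were lower. SCN2B was at least 215-fold, B3GAT1 at least 73.5-fold and BMP6 at least 66.3-fold higher than in untreated cells. CCL20 (0.28 ± 0.23, adjusted p = 0.37), TLR2 (0.08 ± 0.05, adjusted p = 0.26) and the brightest probe of PTAFR (0.02 ± 0.11, adjusted p = 0.92) did not pass the test. The other probe of PTAFR gave 0.71 ± 0.10 (limma adjusted p = 0.0012).

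**Figure D2:**
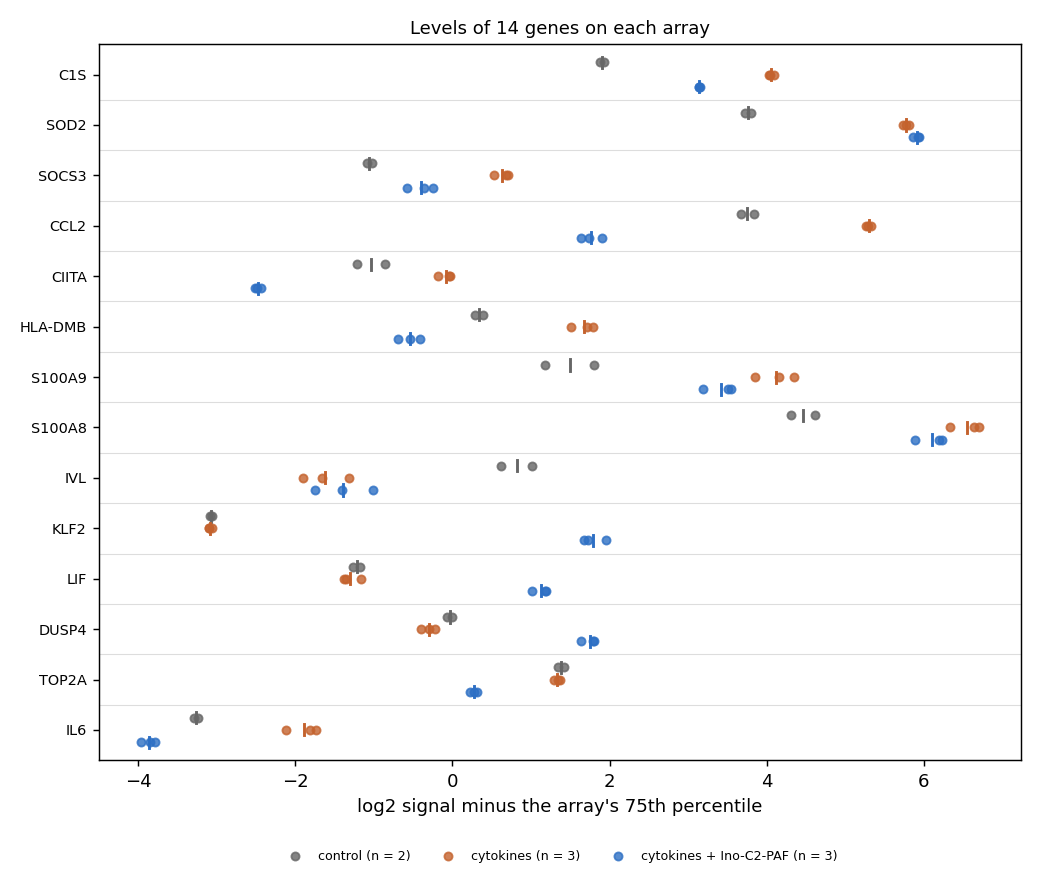
Level of 14 genes on each of the 8 arrays, as log2 signal less the array's 75th percentile; each point is 1 array and each vertical bar a group mean. CCL2 stood at a mean of 5.30 with cytokines and 1.76 with Ino-C2-PAF, and KLF2 at -3.09 and 1.79.

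Against untreated cells, 14 of the 30 lists passed camera and none passed with an estimated correlation (lowest adjusted p = 0.118). Of 18 antimicrobial genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 3.8e-04, and adjusted p = 0.412 with an estimated correlation). Of 28 STAT3 targets, 19 rose and 2 fell (19 and 2 adjusted over the list alone; camera adjusted p = 4.5e-06, and adjusted p = 0.118 with an estimated correlation). Of 43 cytokines and receptors, 22 rose and 11 fell (22 and 11 adjusted over the list alone; camera adjusted p = 0.0070, and adjusted p = 0.343 with an estimated correlation). Of 28 antigen presentation genes, 12 fell (12 adjusted over the list alone; camera adjusted p = 1.9e-04, and adjusted p = 0.439 with an estimated correlation). Of 40 cell cycle genes, 38 fell (38 adjusted over the list alone; camera adjusted p = 6.5e-21, and adjusted p = 0.118 with an estimated correlation). Of 40 DNA replication genes, 28 fell and 1 rose (30 and 1 adjusted over the list alone; camera adjusted p = 4.3e-08, and adjusted p = 0.412 with an estimated correlation). Cholesterol synthesis genes rose in 24 cases and fell in 2 of 28 (25 and 2 adjusted over the list alone; camera adjusted p = 3.1e-12, and adjusted p = 0.147 with an estimated correlation). Fatty acid genes rose in 21 and fell in 6 of 44 (22 and 8 adjusted over the list alone; camera adjusted p = 0.0036, and adjusted p = 0.118 with an estimated correlation). Cornified envelope genes rose in 12 of 17 cases (13 adjusted over the list alone; camera adjusted p = 3.4e-05, and adjusted p = 0.169 with an estimated correlation). Growth factor genes rose in 20 and fell in 4 of 30 (20 and 4 adjusted over the list alone; camera adjusted p = 1.6e-05, and adjusted p = 0.169 with an estimated correlation). Basal keratinocyte genes (17 rose, 8 fell of 32), oxidative stress genes (16 and 4 of 29), endothelial markers (3 of 4 rose) and unfolded protein genes (19 and 6 of 37) passed with camera adjusted p of 0.021, 0.0035, 0.019 and 0.047, and with an estimated correlation gave adjusted p of 0.373, 0.288, 0.179 and 0.634. Adjusted over the list alone, their counts were 20 and 9, 16 and 4, 3 and 20 and 6. Interferon-induced genes were on both sides of the untreated level, with 5 that rose and 13 that fell of 44 (4 and 12 adjusted over the list alone; camera adjusted p = 0.160). So were acute-phase genes, with 8 and 3 of 22 (8 and 3 adjusted over the list alone; camera adjusted p = 0.109). The other 14 lists did not pass camera, with adjusted p between 0.108 and 0.946. The matrix list had a median of -0.02 and a mean of 0.33, and the platelet-activating factor list a median of 0.02, whose sign changed between scalings, and a mean of -0.05.

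Over all genes, 4179 rose and 4026 fell against untreated cells, 623 and 608 of them at least 2-fold, and groups did not overlap for 62.1% of genes, where chance gives 20%. The row as a block left 1728 and 1649 genes, and ended the calls of SOCS3 (0.66 ± 0.11, adjusted p = 0.095 with the block), CCL7 and the unfolded protein list (0.14), while the acute-phase list gained one (0.013). CCL7 also lost its call after normexp background correction with an offset of 50 (-0.22, where IL6 gave -0.34) and without control 1 (0.13), Ino-C2-PAF 2 or Ino-C2-PAF 3, and S100A7, at 1.12 ± 0.28 (adjusted p = 0.017), without control 2 (0.11). The interferon list was called as lower without control 2 (adjusted p = 0.0090) and the acute-phase list as higher without control 1 (0.020). On all arrays these lists had adjusted p = 0.794 and adjusted p = 0.542 with an estimated correlation. The unfolded protein list lost its call after quantile normalization (0.060) and without control 1 (0.056), cytokines 2 (0.054), Ino-C2-PAF 2 (0.10) or Ino-C2-PAF 3 (0.065).

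Among the 571 genes that cytokines raised, Ino-C2-PAF lowered 242, among them CCL2, CIITA, C1S, C1R and NNMT, raised 188 further, among them SCN2B, EBI3 and ALOX12B, and left 141 without a call. Lists drawn independently would share 108 and 120. Of the 549 genes that cytokines lowered, Ino-C2-PAF raised 109, among them MMP10 and KLK7, and lowered 281 further, where independent lists would share 115 and 104. The cytokine arrays enter both changes with opposite signs, which by itself favours opposite calls. Between Ino-C2-PAF arrays and untreated cells, 383 of the 571 raised genes were also higher, 60 were lower and 128 were not called, where independent lists would share 124 and 119. Their median was 0.54 with cytokines and 0.48 with Ino-C2-PAF. Of the 549 lowered genes, 453 were also lower, 30 were higher and 66 were not called, where independent lists would share 115 and 119, and their median was -0.50 and -0.75. The first comparison shares both untreated arrays with this last one, which by itself favours calls in the same direction. Across genes, their changes correlated at r = 0.533, below the mean of 0.602 (SD 0.0150) over 100 draws of simulated groups without any change, while their covariance was 0.0894, above the mean of 0.0184 in the same draws. Genes are not independent replicates. Across them, the changes of the first and second comparisons correlated at r = 0.038, against a mean of -0.444 (SD 0.0196) when no group changed. The simulated changes are noise alone, which makes r larger in size, so the gap in r overstates the difference. Their covariance was 0.0054, against a mean of -0.0121 (SD 0.00074) in the same draws. Within slide rows, with no cytokine array shared, r was 0.0952. In place of 0.038, r was -0.157 without a filter on dim probes, -0.0054 without cytokines 1, -0.023 without cytokines 3, 0.0096 without control 1 and 0.018 without cytokines 2. With the row as a block, 118 raised genes were lowered by Ino-C2-PAF and 81 raised further, and 39 lowered genes were raised and 118 lowered further. In the same order, these counts were 165, 82, 53 and 96 without control 1 and 119, 77, 41 and 100 without control 2. They were 151, 100, 62 and 158 without cytokines 1, 133, 70, 47 and 124 without cytokines 2, and 161, 82, 53 and 139 without cytokines 3.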

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

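Of the tests in this part, fry was chosen only after the results were seen; the other alternatives were fixed before the data were examined. The deposited table gave identical results, and quantile normalization, probes well above background on all arrays, the mean of all passing probes and array weights left every count of genes and overlap within 1.5 times the values reported. No gene was called in opposite directions under any alternative, except for 1 gene in the first comparison and 3 in each of the others with the mean of all passing probes, and the median of all genes stayed within 0.1 of 0 on the log2 scale. That mean turned PTAFR to 0.33 when Ino-C2-PAF was added, because it averages probes that differ. Dim signal limits the rest: CXCL8 was not well above background on any array, and changes of dim genes depend on the background correction. Of 106, 159 and 168 named calls, 30, 113 and 141 stayed under the adjusted p threshold in every alternative that gave the gene a value; the fold of at least 2 was applied to counts only. In turn, leaving out 1 array ended 46, 16 and 12. Same-numbered arrays with and without Ino-C2-PAF deviated together at r of 0.093, 0.0996 and 0.159. Differently numbered ones gave r between -0.104 and -0.002, so the same-numbered pairs were the highest. Same-numbered pairs with an untreated array gave r between -0.199 and 0.091. These values leave open whether the numbers are pairs. The labels do not say so, and pairs were not assumed. The lists were run with quantile normalization, normexp, either block, an estimated correlation, fry and each array left out; of these, only the estimated correlation ended list calls in the second comparison.

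In the values below, raised-lowered stands for genes raised by cytokines and lowered by Ino-C2-PAF, and so on; where no reason is given, the cause was not tested. With normexp, lowered-raised was 61. The median shift gave 65 lowered-raised and 121 raised-raised. Without a filter, 34788 genes were tested, 270 rose and 207 fell with cytokines, raised-lowered was 123, lowered-raised 29, raised-raised 65, lowered-lowered 94 and r -0.157. With only the groups compared, 355 fell with cytokines, lowered-raised was 59 and raised-raised 117. With trend and robust options, 869 fell with cytokines, lowered-raised was 185, raised-raised 302 and lowered-lowered 438. The replicate block gave 363 and 316 with cytokines, lowered-raised 61, raised-raised 109 and lowered-lowered 172. The slide row block gave 327 and 271 in the first, 2239 and 2067 in the second and 1728 and 1649 in the third comparison, raised-lowered 118, lowered-raised 39, raised-raised 81, lowered-lowered 118 and r 0.0952. The slide row holding both groups, with fewer arrays, gave 57 and 34, then 1255 and 1099, raised-lowered 24, lowered-raised 4, raised-raised 8, lowered-lowered 13 and r 0.0952; the third comparison could not be made, since no row holds both its groups. A fold of at least 2, stricter by construction, gave 98 and 78, 478 and 374, and 623 and 608, raised-lowered 30, lowered-raised 8, raised-raised 13 and lowered-lowered 25. Of 90 list tests, 44 were called, 1 with the correlation estimated and 68 with fry, which asks whether a list moves and not whether it moves more than other genes.

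Leaving out 1 array gave 251 to 513 and 186 to 516 in the first comparison, 3275 to 3915 and 2907 to 3530 in the second, and 3105 to 4006 and 2946 to 3780 in the third. Raised-lowered ranged from 119 to 209, lowered-raised from 41 to 100, raised-raised from 70 to 159, lowered-lowered from 96 to 248, r from -0.023 to 0.060 and called lists from 40 to 44.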

Other observations

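Of the tests in this part, the scan of gene families by symbol was chosen only after the results were seen. Among 337 families, the small proline-rich proteins stood out when Ino-C2-PAF was added: 8 of 8 SPRR genes rose (limma), with a median of 2.05 (camera adjusted p = 3.3e-04, and adjusted p = 0.867 with an estimated correlation). Probes were not realigned, so signal shared between similar SPRR genes was not excluded. Intraflagellar transport genes, which build cilia, were lower, with 12 of 17 IFT genes called and a median of -0.36 (camera adjusted p = 0.0018, and adjusted p = 0.867 with an estimated correlation). Of 6 DLX homeobox genes, 4 fell, DLX5 by 2.09 ± 0.08 on the log2 scale, with a family median of -0.76 (camera adjusted p = 0.020, and adjusted p = 0.867 with an estimated correlation). Of 12 NDUFA genes of respiratory complex I, 8 fell, with a median of -0.21 (camera adjusted p = 0.012), and of 14 PSMD genes of the proteasome's regulatory particle, 8 rose, with a median of 0.16 (camera adjusted p = 0.042). The NDUFA and PSMD families each had adjusted p = 0.867 with an estimated correlation. None of the IFT, DLX, NDUFA and PSMD medians changed sign under the other scalings.

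Genes chosen after their values were seen extend the lists described above. When Ino-C2-PAF was added, the interleukin genes IL1A and IL1B rose by 1.97 and 1.80, the growth factor CSF2 by 2.97 and the matrix proteases MMP1 and MMP9 by 2.40 and 2.08, while MMP13 fell by 2.14 on the log2 scale. The phosphatases DUSP5 and DUSP6, which MAP kinase signalling induces, rose by 2.45 and 2.63, and the class II genes HLA-DRA, HLA-DQA1 and CD74 fell by 1.57, 1.79 and 1.53. The endothelial markers CLDN5, ROBO4 and VWF rose, but TEK, KDR, TIE1, ERG and EMCN were well above background on 0 of 8 arrays, as were the immune markers CSF1R, CD163 and MS4A1 and the fibroblast markers COL1A2, COL3A1 and PDGFRA. Other members of the same lists were well above background on 8 of 8 arrays. These were CDH5 and VWF of the endothelial markers and CD4, CD8A, CD79A, CD68, TYROBP and LAPTM5 of the immune markers. The fibroblast markers COL1A1, FAP, FBLN1, DPT, TWIST2 and S100A4 were so too. CLDN5 was well above background on 6 of 8 and ROBO4 on 4 of 8. The filter keeps genes detected throughout 1 group only, which favours such genes in the endothelial list test.

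Cell cycle and DNA replication genes were lower with Ino-C2-PAF, with a list score of -0.672 (SE 0.033). The score is taken less the median of all genes, so an array-wide shift cancels and the score cannot test one. Quantile normalization gave -0.665 (SE 0.034) and the normexp background correction -0.606 (SE 0.030). Without that subtraction, the cell cycle median lay between -0.86 and -0.78 under the 4 scalings. The DNA replication median lay between -0.53 and -0.46. With the slide row as a block the score was -0.653 (SE 0.053). The choice among these scalings does not account for the lower level. The block estimate rests on cytokines 3, the only cytokine array in the slide row of the Ino-C2-PAF arrays. The score stayed lower within that row, but with that array alone the slide row was not excluded. An effect of Ino-C2-PAF stays open as a hypothesis, found and tested on the same arrays.

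Interferon and antigen presentation genes were lower by a list score of -0.796 (SE 0.081). An array-wide shift cancels in this score too, so the score cannot test one. The normexp background correction gave -0.698 (SE 0.066) and the slide row as a block -0.692 (SE 0.113). Leaving out the cytokine array that mattered most, cytokines 2, gave -0.748 (SE 0.096). Without the subtraction of the all-gene median, the interferon median lay between -0.79 and -0.70 under the same scalings. The antigen presentation median lay between -0.76 and -0.64. These values argue against the choice among these scalings as the whole cause. The block estimate rests on cytokines 3, the only cytokine array in the slide row of the Ino-C2-PAF arrays. The score stayed lower within that row, but with that array alone the slide row was not excluded. Leaving out an array cannot test chance values of the shared cytokine arrays, because the remaining ones keep any deviation they share. An effect of Ino-C2-PAF stays open as a hypothesis, found and tested on the same arrays, and no mechanism was tested.

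Cholesterol synthesis genes were higher by a list score of 0.713 (SE 0.021). Here too an array-wide shift cancels in the score, so the score cannot test one. Quantile normalization gave 0.712 (SE 0.020) and the slide row as a block 0.759 (SE 0.028). Without the subtraction of the all-gene median, the list median lay between 0.82 and 0.86 under the same scalings. These values argue against the choice among these scalings as the cause. The block estimate rests on cytokines 3, the only cytokine array in the slide row of the Ino-C2-PAF arrays. The score stayed higher within that row, but with that array alone the slide row was not excluded. An effect of Ino-C2-PAF stays open as a hypothesis, and the design holds no Ino-C2-PAF without cytokines.

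The 7700 genes called when Ino-C2-PAF was added were set beside the 10 splits of the 6 arrays into 3 and 3. In 1 of the 10, the real one, that many genes were called, and the highest of the others was 0 by limma, with 793 genes at unadjusted p under 0.05 against 9191 in the real split. Each other split puts arrays of both treatments in both groups, so the treatment difference enters the spread and few calls follow by design. The contrast therefore does not measure chance, and the splits are too few for a share under 0.05.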
